A study of Caenorhabditis elegans with 6 samples.

How the data were processed

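Gene expression was measured in whole L4 larvae (the last larval stage) of *Caenorhabditis elegans* with Affymetrix single-colour expression arrays. There were 3 arrays of the alg-1(gk214) mutant and 3 of the N2 wild type strain. Per the labels' protocols, synchronized worms grew at 25 °C on bacterial food, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from about 5 µg of total RNA. The labels call the 3 replicates of each genotype independent.

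The deposited table holds 1 log2 value per probe set and array, made by the authors with Affymetrix Power Tools, per the submitters' processing notes. The version of that tool and the methods of background correction, normalization and summarization are not given in the sources used here. The log2 scale was taken from the values, which ran from 3.14 to 14.9. Medians of the 3 mutant arrays were 6.02, 6.01 and 6.02, and medians of the 3 wild type arrays were 6.02, 6.01 and 6.05. The values were therefore used as deposited, with no further normalization. No detection calls were used here, and the number of arrays limits the precision.

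The table has 22625 probe sets. The 77 Affymetrix control probe sets were left out of the tests, which leaves 22548. Gene names came from the platform annotation, updated by gene identifier through a RefSeq gene table of assembly WBcel235, in which 20701 probe sets matched. That table served for names alone, and no coordinates are given. Of the probe sets tested, 20766 had 1 gene symbol, 887 had several and 895 had none. No gene was named from a probe set with several symbols. Each gene was represented by its single-symbol probe set with the highest mean over the 6 arrays, which gave 17118 genes. Affymetrix marks probe sets whose probes match several transcripts with the endings _s_at (5484 probe sets) and _x_at (1227 probe sets).

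Mutant minus wild type was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with its default prior), two-sided, with Benjamini-Hochberg adjustment over the 22548 probe sets and a threshold of 0.05. All adjusted p-values of single genes come from that limma model. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. Values are given as mean ± SD over the 3 arrays of a group, and changes as log2 differences with their standard error (SE). Fold changes are the log2 differences raised from base 2.

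The 30 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way. Listed genes with no matching symbol counted as not measured. The comparison, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

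The named genes are alg-1, alg-2, lin-14, lin-28, lin-41, hbl-1, daf-12 and col-19, whatever their values. Added to these are the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold. For these, all 3 mutant values lay on one side of all 3 wild type values and the mean of the higher group lay above the median of all probe sets. Up to 4 members with the smallest p were named from each list described.

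The alternatives were quantile normalization, median centring, filters at the median and the 25th percentile of expression, an intensity trend with a robust prior, array weights, removal of probe sets ending in _s_at or _x_at, a threshold of 0.01, replicate number as a block, and leaving out each array in turn. For the lists, the mean of all probe sets of a gene was also used. Centring on the bacterial hybridization controls, list tests on probe sets without these endings, and the mean over probe sets for alg-1 and alg-2 were added after the data were seen. A planned test of miRNA seed matches needs 3′ UTR sequences, which were not used here.

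The limma step was tested on simulated data for the comparison of mutant with wild type, with 22548 probe sets. It recovered 47.8% of 67 simulated changes of 0.5 log2, 89.6% of 67 changes of 1 log2 and 100% of 66 changes of 2 log2. Of 163 calls, 5 were false. The simulated changes covered a far smaller share of the probe sets than the 33.7% called in the data, so these rates may differ there. The camera step was tested on 17118 simulated genes for the same comparison. It called a list of 50 genes shifted by 0.5 log2 and called 0 of 200 unchanged lists. The simulated genes varied independently, while the estimated correlation in the data was 0.26 for the sperm list. The simulation therefore does not cover lists whose genes vary together.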

Results

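Whole-worm expression profiles of alg-1(gk214) mutants and of the N2 wild type strain were compared at the L4 stage. ALG-1 is an Argonaute protein that carries microRNAs and acts with them to repress target mRNAs. The series is about genes targeted by ALG-1. The comparison covered all transcripts measured, and it does not identify which of them ALG-1 regulates directly. There were 3 arrays per genotype, with 22548 probe sets tested. Across probe sets, Pearson correlations were 0.998 between all pairs of mutant arrays, 0.994 to 0.996 between wild type arrays, and 0.968 to 0.976 between genotypes. The GAPDH control probe sets gave 3′ minus 5′ differences of −0.19, −0.22 and −0.14 log2 on the mutant arrays and −0.23, −0.23 and −0.58 on the wild type arrays. Wild type replicate 3 therefore stood apart from the other arrays by this measure.

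The mutated gene itself was lower on all 3 mutant arrays. The alg-1 probe set with the highest signal read 5.90, 6.09 and 6.09 log2 in the mutant and 6.80, 6.83 and 6.65 in the wild type. Its level of 6.03 ± 0.11 (SD, n = 3) against 6.76 ± 0.10 (SD, n = 3) was a change of −0.73 (SE 0.085, limma adjusted p = 0.000245). A second alg-1 probe set fell by 0.62 (adjusted p = 0.00977), and another differed by −0.10 (adjusted p = 0.748). The position of these probes relative to the gk214 deletion is not given in the sources used here, so their value as a check of the genotype is limited. The mean over all alg-1 probe sets, a choice made after the data were seen, changed by −0.48 (SE 0.12, adjusted p = 0.0142). The closest paralog, alg-2, which also carries microRNAs, was higher in the mutant, at 8.99 ± 0.12 against 8.59 ± 0.03 (SD, n = 3). This was a change of 0.40 (SE 0.080, adjusted p = 0.00481), and its second probe set rose by 0.22 (adjusted p = 0.037).

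Expression differed widely between the genotypes. Of the probe sets tested, 7591 (33.7%) passed the threshold, 3340 of them higher and 4251 lower in the mutant, so that 44% of the changed probe sets were higher. At a change of 2-fold or more there were 1095 probe sets, 685 higher and 410 lower. Counted as genes, 2466 of 17118 rose and 3449 fell, and 549 of the rises and 331 of the falls reached 2-fold. The counts of rises and falls within gene lists are to be read against these shares. The balance of higher and lower calls depended on the scaling. When arrays were centred on the bacterial hybridization controls, a choice made after the data were seen, 7099 probe sets passed and 68.4% of them were higher. That centring moved the median change over all probe sets from −0.05 to 0.08, and small changes are to be read relative to this shift. The counts were 5443 without mutant replicate 1, 7833 without wild type replicate 1 and 7345 without wild type replicate 3.

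The largest rises among the named genes were 14-fold or more. The steepest was spia-1, at 10.4 ± 0.15 in the mutant against 6.11 ± 0.11 in the wild type (SD, n = 3), a change of 4.25 (SE 0.095, adjusted p = 7.32e-08). Next came Y37A1B.7 (4.22), far-3 (4.13), which encodes a fatty acid and retinol binding protein, C14A4.9 (4.02) and wrt-4 (3.97), a hedgehog-related gene. The others were F33D4.6 (3.93), H42K12.3 (3.91), bah-1 (3.86), K08E7.5 (3.86) and F58H1.2 (3.83), all on the log2 scale. The steepest fall among the named genes was that of T13F3.6, from 9.73 ± 0.23 to 5.63 ± 0.19 (SD, n = 3), a change of −4.10 (SE 0.13, adjusted p = 1.44e-07). It was followed by the major sperm protein genes msp-36 (−3.32), msp-76 (−3.19), msp-78 (−3.18), msp-38 (−3.16) and msp-77 (−3.03), by T10E9.4 (−3.28) and F37A4.5 (−3.23), and by the heat shock genes hsp-16.41 (−3.23) and hsp-70 (−3.22).

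**Figure D1:**
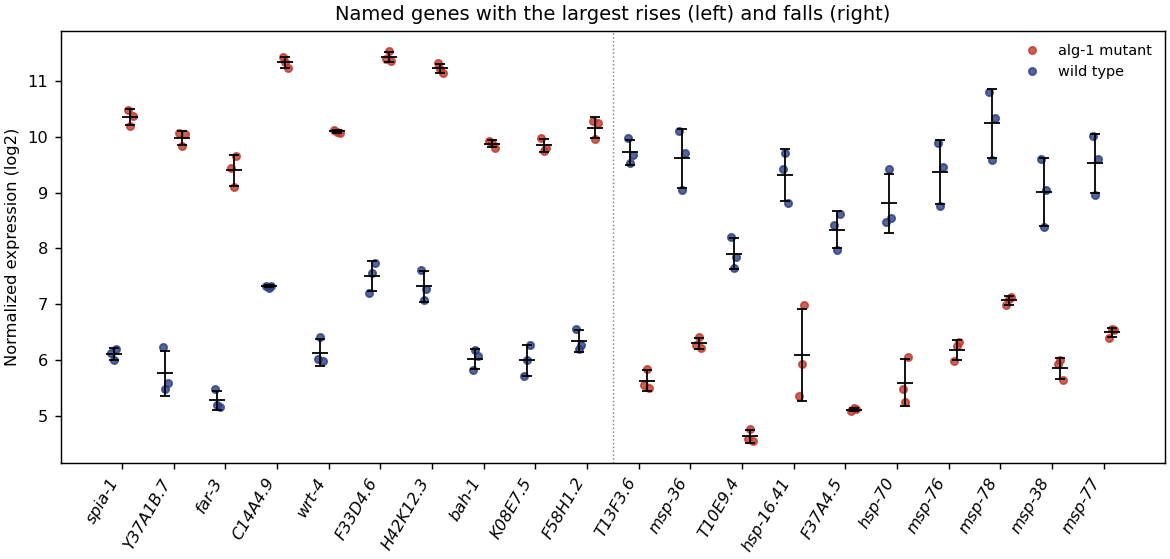
Normalized expression (log2) on each array for the named genes with the 10 largest rises (left) and 10 largest falls (right). Points are arrays, with mutant in red and wild type in blue, and bars are the mean ± SD of 3 arrays. The mutant and wild type points of each gene do not overlap, from a change of 4.25 for spia-1 to −4.10 for T13F3.6.

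Genes that control developmental timing in the larva, the heterochronic genes, were mostly higher in the mutant. Of 17 measured, 12 rose and 2 fell, with the same counts adjusted over the list alone, and the median change was 0.64 log2 (camera adjusted p = 4.37e-06). With an estimated correlation this list gave adjusted p = 0.133, and its median was 0.42 with the mean of all probe sets of a gene. The nuclear hormone receptor gene daf-12 rose 3.34-fold, from 7.56 ± 0.10 to 9.29 ± 0.23 (SD, n = 3; change 1.74, SE 0.12, adjusted p = 1.10e-05). The Period-related gene lin-42 rose by 1.97 (adjusted p = 6.57e-06), hbl-1 by 1.22 (SE 0.18, adjusted p = 0.000848), lin-46 by 1.01 and lin-66 by 0.77. The microRNA targets lin-41 and lin-28 rose by 0.98 (SE 0.11, adjusted p = 0.00017) and 0.64 (SE 0.11, adjusted p = 0.00273). The remaining lin-28 probe sets, both of low signal, differed by −0.09 and −0.04 and did not pass, and a low daf-12 probe set differed by −0.09. Second probe sets gave smaller rises, of 0.98 for daf-12, 0.70 for hbl-1 and 0.47 for lin-41, all past the threshold. The lin-14 probe set, at the 21.8th percentile of expression, where changes are hard to detect, differed by 0.00 (SE 0.068, adjusted p = 0.991). The adult cuticle collagen gene col-19 differed by −0.12 (SE 0.079, adjusted p = 0.305).

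**Figure D2:**
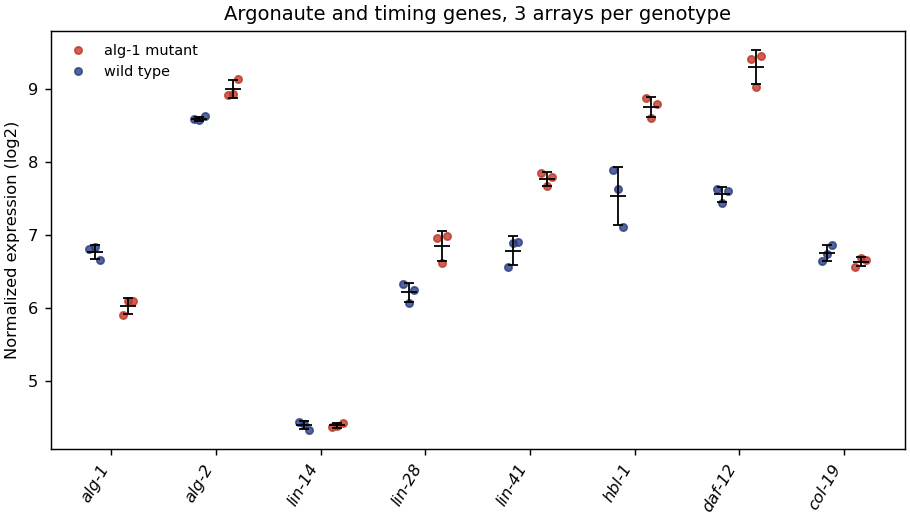
Normalized expression (log2) on each array for alg-1, alg-2, 5 timing genes and the collagen gene col-19. Points are arrays, with mutant in red and wild type in blue, and bars are the mean ± SD of 3 arrays. The alg-1 points are lower in the mutant (change −0.73), those of daf-12 are higher (1.74), and those of lin-14 overlap.

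Genes reported as microRNA targets, of which 5 are also in the timing list, gave a smaller difference. Of 22 measured, 10 rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000871; adjusted p = 0.164 with an estimated correlation). Besides daf-12 and lin-41, the zinc finger gene die-1 rose by 1.14 (SE 0.091, adjusted p = 2.89e-05), while the cadherin gene cdh-3 fell by 0.57 (adjusted p = 0.000661). Of 21 genes of the microRNA pathway, 4 rose and 3 fell, with the same counts adjusted over the list alone, and the list did not pass (median −0.01, camera adjusted p = 0.655). In this list ain-1, whose protein binds ALG-1, rose by 0.56 (adjusted p = 0.000438) and the exonuclease gene xrn-1 fell by 0.47 (adjusted p = 0.00847). The xrn-1 signal was low, at percentile 33.1 of expression.

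Genes of the molting cycle and hedgehog-related genes were higher. Of 25 molting genes, 15 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 6.56e-10; adjusted p = 0.133 with an estimated correlation). Examples were mlt-9 (3.66, SE 0.11, 12.6-fold), mlt-10 (2.74), che-14 (2.28), and nas-37 (2.74), which encodes a metalloprotease needed to shed the old cuticle. Of 82 hedgehog-related and patched-related genes, 45 rose and 8 fell (46 and 10 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.60e-13; adjusted p = 0.133 with an estimated correlation). Their median was 0.15 on probe sets without the _s_at or _x_at ending (camera adjusted p = 3.6e-08) and 1.21 above the median expression. They included wrt-1 (3.76), grl-15 (3.55) and grd-1 (2.65), with adjusted p-values of 7.32e-08, 7.32e-08 and 1.09e-07. Among wild type replicates 1, 2 and 3, the mean of the molting genes deviated from the group mean by 0.22, −0.12 and −0.10 log2, and that of the hedgehog-related genes by −0.05, 0.02 and 0.04.

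Cuticle collagens changed in both directions. Of 146 measured, 47 rose and 34 fell (52 and 37 adjusted over the list alone). The median was 0.04 and the mean 0.32 log2, and the list passed as higher (camera adjusted p = 0.00506), with adjusted p = 0.583 with an estimated correlation. The median was 0.013 without mutant replicate 2, 0.0094 without wild type replicate 1 and 0.070 without wild type replicate 3. It was 0.074 with quantile normalization, 0.11 above the median expression and 0.17 with centring on the hybridization controls. The 128 genes with the prefix col, grouped after the data were seen, gave 32 rises and 34 falls. Their median was −0.02, and camera, adjusted over 390 such families, did not call them (adjusted p = 0.42). Outside this group, larger rises included sqt-1 (3.24, SE 0.066), rol-6 (2.71), rol-8 (2.53) and lon-3 (2.49). Of 19 hypodermis and seam genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.23, camera adjusted p = 0.00506, adjusted p = 0.133 with an estimated correlation). On probe sets without the _s_at or _x_at ending the median was 0.13. The fusogen gene eff-1 (1.34), lin-26 (0.90) and ceh-16 (0.77) were among those that rose.

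Transcripts of sperm and germline genes were lower in the RNA of whole mutant worms. Such RNA cannot tell lower expression per cell from a smaller share of these cells. Of 79 sperm genes, 0 rose and 59 fell (0 and 61 adjusted over the list alone), with a median of −0.58 (camera adjusted p = 5.41e-15; adjusted p = 0.175 with an estimated correlation). Among wild type replicates 1, 2 and 3, the mean of the sperm genes deviated from the group mean by 0.20, −0.21 and 0.01 log2. The sperm phosphatase genes gsp-3 and gsp-4 changed by −2.44 (SE 0.13) and −2.16 (SE 0.10), with adjusted p-values of 2.52e-06 and 1.31e-06. Both were read from probe sets ending in _x_at, so these may not be separate measurements. All 23 measured major sperm protein genes fell, with a median of −2.30, but 22 of them had only probe sets ending in _s_at or _x_at. The exception, msp-32, was named after its values were seen. Its shared probe set fell by 1.06 (adjusted p = 0.000907), while its own, at the 31.7th percentile of expression, differed by −0.08 (adjusted p = 0.526). On probe sets without these endings the sperm list had 37 genes, 20 of which fell, with a median of −0.28 (camera adjusted p = 2.3e-05). Above the median expression the list's median was −1.91. Of 54 germline and oogenesis genes, 0 rose and 38 fell (0 and 39 adjusted over the list alone), with a median of −0.41 (camera adjusted p = 6.56e-10; adjusted p = 0.133 with an estimated correlation). Examples were the meiotic gene him-3 (−1.18, SE 0.091), the P granule genes glh-4 (−1.16) and pgl-1 (−0.88), and oma-1 (−0.81), which acts in oocytes. Of 49 genes of other small RNA pathways, 2 rose and 19 fell (2 and 20 adjusted over the list alone; median −0.16, camera adjusted p = 0.00506, adjusted p = 0.133 with an estimated correlation). This median was −0.03 with centring on the hybridization controls (camera adjusted p = 0.00801). Those that fell included the Argonaute genes alg-4 (−1.55), known to act in sperm formation, wago-10 (−1.45), wago-2 (−0.84) and ppw-2 (−0.58).

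Heat shock and chaperone genes were lower. Of 60 measured, 7 rose and 29 fell (7 and 33 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.0016; adjusted p = 0.164 with an estimated correlation). The median was −0.09 with centring on the hybridization controls (camera adjusted p = 0.000811). The stress-inducible genes hsp-70, hsp-16.41 and hsp-16.2 changed by −3.22 (SE 0.27), −3.23 (SE 0.37) and −2.87 (SE 0.30), with adjusted p-values of 4.06e-05, 0.000252 and 0.000151. The other measured hsp-16 genes, named after their values were seen, did not pass: hsp-16.20 (0.22, adjusted p = 0.112) and hsp-16.21 (−0.02, adjusted p = 0.847). Any hsp-16 gene without a single-symbol probe set was not measured. The small heat shock gene hsp-43 fell by 1.07 and dnj-13 by 0.77.

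Of 33 proteasome genes, 0 rose and 8 fell (0 and 7 adjusted over the list alone; median −0.18, camera adjusted p = 0.00255, adjusted p = 0.236 with an estimated correlation). Under centring on the hybridization controls the median was −0.05 (camera adjusted p = 0.0195). The subunit gene rpn-6.2 fell by 2.13 (SE 0.092), far more than any other member. By contrast rpn-6.1, named after its values were seen, differed by −0.10 (adjusted p = 0.36). Smaller changes were those of rpt-6, pas-7 and pas-5, at −0.40, −0.38 and −0.33. The same centring left pas-5 short of the threshold (−0.20, adjusted p = 0.122). Of 38 mitochondrial respiration genes, 0 rose and 7 fell, with the same counts adjusted over the list alone (median −0.11, camera adjusted p = 0.0283, adjusted p = 0.409 with an estimated correlation). Over all 17118 genes, 2466 rose and 3449 fell. The share of falls in the proteasome and respiration lists was thus near that of all genes, while both lists had 0 rises. Within the respiration list, the cytochrome c gene cyc-2.2 fell by 2.09 (SE 0.17) and ucr-2.3 by 0.78. The respiration list was no longer past the threshold without wild type replicate 1 (adjusted p = 0.151) or with centring on the hybridization controls, where its median turned to 0.02 (adjusted p = 0.135).

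Neuropeptide genes tended upward. Of 109 measured, 45 rose and 9 fell (49 and 9 adjusted over the list alone; median 0.19, camera adjusted p = 4.37e-06, adjusted p = 0.152 with an estimated correlation). The insulin-like gene ins-35 rose by 3.07 (SE 0.12) and flp-8 by 0.97, while nlp-26 (−1.90) and nlp-27 (−0.83) fell. By prefix, grouped after the data were seen, 14 of 25 flp genes rose and 1 fell, and 25 of 58 nlp genes rose and 6 fell. Of 23 ins genes, 4 rose and 2 fell (median 0.01, camera adjusted p = 0.268), so ins-35 does not stand for its family. The list shares 7 genes, nlp-27 among them, with the innate immunity list. Of 36 neuronal genes, 8 rose and 1 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.00823, adjusted p = 0.164 with an estimated correlation). They included unc-13 (0.77), which acts in synaptic vesicle release, and the neuropeptide processing genes egl-3 (0.44) and egl-21 (0.40). On probe sets without the _s_at or _x_at ending the neuronal median stayed at 0.08, but the list did not pass (camera adjusted p = 0.0551). Of 37 insulin and dauer genes, 13 rose and 4 fell (13 and 5 adjusted over the list alone; median 0.09, camera adjusted p = 0.00506, adjusted p = 0.133 with an estimated correlation). The median was 0.052 without mutant replicate 1, 0.059 without wild type replicate 2 and 0.057 with the mean of all probe sets of a gene, but 0.22 with centring on the hybridization controls. Besides daf-12, daf-6 (2.73, SE 0.089), sod-4 (0.86) and daf-7 (0.54) rose.

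Of 61 intestinal genes, 21 rose and 10 fell (23 and 10 adjusted over the list alone; median 0.07, camera adjusted p = 0.00506, adjusted p = 0.133 with an estimated correlation). The median was 0.13 without mutant replicate 2, 0.20 without wild type replicate 3, 0.12 with quantile normalization, 0.23 above the median expression and 0.20 with centring on the hybridization controls. The metallothionein gene mtl-1 rose 11.6-fold (3.53, SE 0.22), cpr-6 rose by 1.85 and the lysozyme gene lys-7 by 1.35, while pho-8 fell by 1.98. Of 35 histone genes, 15 rose and 4 fell (18 and 5 adjusted over the list alone; median 0.25, camera adjusted p = 0.00352, adjusted p = 0.485 with an estimated correlation). The members with the smallest p went both ways: his-70 (−1.40), hil-4 (−0.76) and hil-5 (−0.64) fell and hil-7 rose by 0.69. Histone genes share probes, and on probe sets without the _s_at or _x_at ending the median was −0.02 (camera adjusted p = 0.89). Fry gave adjusted p = 0.0752 for histones.

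The remaining lists did not pass camera's threshold. Of 5 vitellogenin (yolk protein) genes, 0 rose and 3 fell, with the same counts adjusted over the list alone (median −0.34, camera adjusted p = 0.0895, fry adjusted p = 0.00451). The changes were −0.47 for vit-6, −0.34 for vit-4 and −0.81 for vit-1. The vit-6 probe set ends in _s_at and the vit-4 probe set in _x_at, so their probes may also match other transcripts. Signals of vit-4 and vit-1 were low, at percentiles 35.6 and 37.5 of expression, so their changes are less certain. Without mutant replicate 1 or 3, vit-1 changed by −0.78 in each case but no longer passed (adjusted p = 0.0579 and 0.0598). With centring on the hybridization controls vit-4 gave −0.21 and did not pass (adjusted p = 0.0779). Lipid metabolism genes went both ways, with 22 rising and 26 falling of 92 (23 and 26 adjusted over the list alone; median −0.03, mean 0.15, camera adjusted p = 0.362). Among these elo-4 (3.26), lips-9 (2.22) and acs-20 (2.11) rose. Of 296 innate immunity genes, 51 rose and 35 fell (49 and 34 adjusted over the list alone; median −0.05, mean 0.07, camera adjusted p = 0.381), with rises of spp-13 (3.73), clec-61 (3.69) and clec-42 (3.59). Among genes above the median expression this list passed as higher (median 0.20, adjusted p = 0.0018), with adjusted p = 0.285 with an estimated correlation. Of 193 detoxification genes, 40 rose and 48 fell (41 and 51 adjusted over the list alone; median −0.07, camera adjusted p = 0.918, fry adjusted p = 0.00689), with ugt-18 at 1.82 and ugt-13 at −1.73. The pharynx list of 79 genes holds 47 pqn and 11 abu genes, taken in by symbol prefix. In this list 18 rose and 16 fell (18 and 17 adjusted over the list alone). The median was −0.04 and the mean 0.02 (camera adjusted p = 0.655), with abu-13 at 3.04 and pqn-94 at −1.87.

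Of 254 nuclear hormone receptor genes, 29 rose and 19 fell (23 and 17 adjusted over the list alone; median 0.00, camera adjusted p = 0.11). The vulva list had 8 rises and 5 falls among 30 genes (8 and 6 adjusted over the list alone; median 0.08, camera adjusted p = 0.201), and lin-11 fell by 0.76. Among 49 cell cycle and DNA replication genes, 7 rose and 9 fell, with the same counts adjusted over the list alone (median −0.02, camera adjusted p = 0.844). The ribonucleotide reductase gene rnr-2 rose by 0.62. Among 16 genes of males, 1 rose and 1 fell, likewise adjusted over the list alone (median −0.03, camera adjusted p = 0.838). Those were mab-5 (0.35) and mab-3 (−0.44). Too few genes of this list lay above the median expression for it to be tested there. Among 30 body muscle genes, 1 rose and 4 fell (0 and 2 adjusted over the list alone; median −0.06, camera adjusted p = 0.986), with unc-45 at −0.42 and atn-1 at −0.44. Of 75 ribosomal protein genes, 0 rose and 1, rpl-11.1, fell (−0.38), with the same counts adjusted over the list alone (median −0.02, camera adjusted p = 0.851). With centring on the hybridization controls rpl-11.1 did not pass (−0.25, adjusted p = 0.0512). Of 1223 serpentine receptor genes, 9 rose and 15 fell, 0 of each adjusted over the list alone (median −0.04, camera adjusted p = 0.95). Only 7 of them lay above the median expression, so the few calls do not show that these genes were unchanged.

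**Figure D3:**
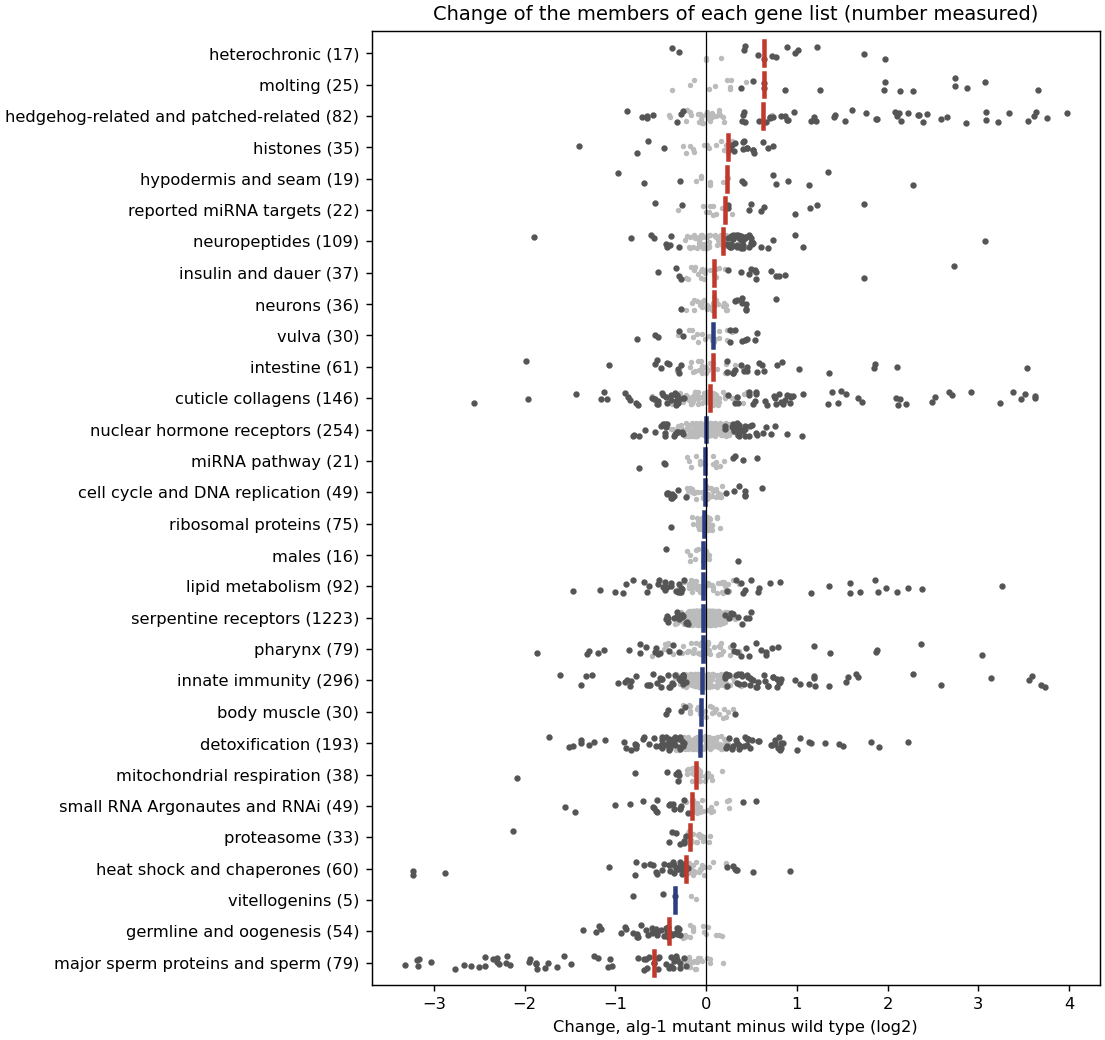
Change of each measured gene (mutant minus wild type, log2) in the 30 gene lists, with the number measured in brackets. Each point is a gene, dark where it passed the threshold, and vertical bars are list medians, red where camera passed at the preset correlation and blue where it did not. Medians run from 0.64 for the heterochronic list to −0.58 for the sperm list.

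In all, 17 of the 30 lists passed camera at the preset correlation, 11 as higher and 6 as lower. With a correlation estimated from the 6 arrays, 0 passed, and the smallest adjusted p was 0.133. By fry, 18 lists moved on balance one way, including 16 of those 17. The median also moved by over 1.5 times with centring on the hybridization controls for neuropeptides (0.32), reported miRNA targets (0.34), histones (0.38), hypodermis and seam (0.36) and neurons (0.21), which all still passed.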

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

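The tests of explanations in this part were chosen after the results were seen, except the count over other splits of the arrays.

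The 77 control probe sets on the array were outside the comparisons, and 6 of them lay higher on all 3 mutant arrays than on any wild type array and passed limma's threshold. The *C. elegans* catalase controls differed by 0.37 (3′ end, adjusted p = 0.00486), 0.47 (5′ end, adjusted p = 0.00646) and 0.29 (middle, adjusted p = 0.0183) log2. The *C. elegans* ubiquitin controls differed by 0.38 (3′ end, adjusted p = 0.00569) and 0.28 (middle, adjusted p = 0.0103). A further control, whose name starts with r2, differed by 0.25 (adjusted p = 0.0282). Another control passed as lower in the mutant, a bacterial hybridization control for bioC (−0.45, adjusted p = 0.00939).

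The count of 7591 changed probe sets was set against other ways of dividing the arrays. The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of these, the real one, gave a count as high. The highest count of the other 9 splits was 0 by limma, with 170 to 652 probe sets at an unadjusted p under 0.05 against 9743 for the real split. With 10 splits the share cannot fall under 0.05. Each of the other splits mixes the genotypes, so the difference between genotypes adds to their within-group spread and lowers their counts. Their low counts therefore do not show what arrays without a genotype difference would give.

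Molting and hedgehog-related genes were higher and sperm and germline genes lower in the mutant. The tables argue against a single scaling factor per array, which would move all lists alike. The gap between the lower of the 2 rising medians and the higher of the 2 falling ones was 1.03 log2 (95% bootstrap interval over genes 0.51 to 1.22). These lists were chosen after their medians were seen, and the interval treats genes as independent. A scaling difference that varies with intensity is not covered by this gap. The tables also argue against probes shared between paralogs as the whole account of the sperm list, whose median on probe sets without the _s_at or _x_at ending was −0.28. On such probe sets the hedgehog-related median was 0.15, against 0.63. For the major sperm protein genes this stays open, since 1 of 23 had such a probe set, and that one, for msp-32, gave −0.08. Collection at different points of the molting cycle cannot be told apart from genotype: over 253 genes, which are not independent replicates, the size of the correlation between the first component of wild type variation (83.2% of it) and the genotype change was 0.20 (95% interval 0.07 to 0.34), neither clearly high nor near 0. A delayed or shifted developmental stage of the mutant, and the loss of alg-1 itself, may also account for it and were not tested apart. Whole-worm RNA also does not separate expression per cell from the share of a tissue in the worm.

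The heat shock genes hsp-16.2, hsp-16.41 and hsp-70 were lower in the mutant. This pattern was narrowed to these 3 genes after hsp-16.20 (0.22) and hsp-16.21 (−0.02) were seen not to pass. A single array does not account for it, since the smallest change over the 6 fits that each left out 1 array was 2.61 log2 in size. The other 57 members of the list had a median of −0.20 (SD 0.34), 7 rising and 26 falling. The median was also −0.20 for the 55 members left when every measured hsp-16 gene was taken out with hsp-70. The other members thus did not fall by nearly as much. These 3 genes have the largest falls of the list, so a smaller fall of the rest was fixed by their choice. A general fall of chaperones may still be part of the pattern. Stress of the wild type cultures at collection may be the source as well as the genotype, and neither was tested.

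Heterochronic genes were higher in the mutant. The expression level of the listed genes does not account for it, since 0 of 10000 random lists matched on mean expression had as high a median, a share of 0.01% with the real list included, the smallest that 10000 lists can give. Without the molting-cycle genes lin-42, nhr-23, nhr-25 and blmp-1, the median of the other 13 was 0.57, with 8 rising and 2 falling. Camera at the preset correlation gave p = 0.000112 for these genes, and p = 0.0298 with an estimated correlation, both unadjusted. The whole list gave adjusted p = 0.133 with an estimated correlation. A lost repression by ALG-1 and a shift in developmental stage may both raise these genes, and no test here separates them.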

How the results depend on the processing

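Centring on the hybridization controls, list tests on probe sets without the _s_at or _x_at ending, and means over probe sets for alg-1 and alg-2 were chosen after the data were seen; the other settings were planned. Of the lists past the threshold, the medians of 2 turned sign where their call was lost: respiration (0.02, centring on the hybridization controls) and histones (−0.02, probe sets without these endings). The innate immunity median turned from −0.05 to 0.20 and passed above the median expression. Of 448 list values under alternatives, 22 lost the call, 17 of them with the estimated correlation, and 3 gained one; of 1965 named-gene values, 16 lost it and 2 gained it. The 7591 changed probe sets became 7740 with quantile normalization, 7531 with median centring, 7628 with a trend and robust prior, 8270 with array weights, 7255 above the 25th percentile and 5636 above the median. Without _s_at and _x_at probe sets, with 15837 tested, there were 4715 (2171 higher, 2544 lower), and below 0.01 there were 4767 (2213 higher, 2554 lower). Centring on the 18 hybridization controls, whose changes ran from −0.45 to 0.08, gave 7099, of which 2242 were lower and 68.4% higher; the cause of the controls' difference was not tested. Leaving out each array gave 5443 to 7833 probe sets, 2444 to 3385 higher and 2999 to 4500 lower.

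With an estimated correlation 0 of 30 lists passed, against 17. This setting leaves the medians as they are and raises p for sperm (−0.58, adjusted p = 0.175), hedgehog-related (0.63, 0.133), molting (0.64, 0.133), germline (−0.41, 0.133), heterochronic (0.64, 0.133), reported miRNA targets (0.20, 0.164), heat shock (−0.22, 0.164) and cuticle collagens (0.040, 0.583). Leaving out each array, 16 or 17 lists passed. With single arrays left out, the changes of alg-1 ran from −0.79 to −0.67 and those of alg-2 from 0.33 to 0.44; with the mean over probe sets they were −0.48 and 0.31.

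Same-numbered arrays of the 2 genotypes deviated together with correlations across probe sets of 0.21, 0.13 and 0.08. Of the 6 arrays, 5 correlated best with their own number in the other genotype, so a shared batch or pairing cannot be excluded. The labels call the replicates independent, and the main fit used no pairing. The replicate block gave 7766 probe sets, 7219 of them shared with the main result in the same direction.

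Seed matches were not run, for want of 3′ UTR sequences here, and pseudocounts do not apply to log2 values. With no detection calls used, changes of low-signal probe sets are the least certain.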

Other observations

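Genes were grouped into families by symbol prefix after the data were seen, and 390 families of 5 or more members, those in the fixed lists included, were tested by camera. Of these, 40 passed, 23 of them with most members outside the lists, 15 higher and 8 lower in the mutant. With an estimated correlation 0 passed, and the smallest adjusted p among the 23 was 0.451. Of 14 bus genes, which affect the surface that bacteria attach to, 13 rose (median 1.33, camera adjusted p = 6.12e-11), with bus-24 at 2.79 and bus-8B at 2.15. Of 7 lpr genes, lipocalin-related, 6 rose (median 2.45), with lpr-5 at 2.83 and lpr-7 at 2.67. Of 6 chitinase genes (cht), 5 rose (median 1.33), and of 8 mam genes 7 rose (median 1.02). All 5 atf transcription factor genes rose (median 0.50), led by atf-2 (2.20) and atf-8 (2.86).

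Of 34 mrpl genes and 25 mrps genes, which encode mitochondrial ribosomal proteins, 28 and 20 fell (medians −0.36 and −0.35, camera adjusted p = 7.78e-07 and 7.42e-05), while the cytosolic ribosomal protein list had 1 fall among 75; the difference between these lists was not tested. In the same comparison 38 of 54 germline and oogenesis genes fell (median −0.41). Of 22 translation initiation factor genes (eif), 18 fell (median −0.29), and of 18 vacuolar ATPase genes (vha), 16 fell and 1 rose (median −0.35), with vha-18 at −0.79 and vha-5 at −0.67. These medians lie further from 0 than the 0.13 log2 by which centring on the hybridization controls moves every gene. That centring would still bring the medians closer to 0, and the counts of falls were not repeated with it. Over all probe sets it left 2242 lower calls, against 4251. Changes in these families were not tested for a cause.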
